A study of Mus musculus with 179 samples.

How the data were processed

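Poly-A RNA of adult mouse brain punches was sequenced with an unstranded TruSeq kit, with multiplexing balanced over groups, per the labels' protocols, so reads of a gene and of its antisense partner cannot be told apart. For NAc males and for all PFC, HIP and female libraries the authors deposited gene counts divided by 1 factor per library, a signal in normalised reads, with HISAT, HTSeq and build mm10 named in the submitters' processing notes without versions. The tool that made the factors is not given in the sources used here. For male VTA the authors deposited RPKM values, and the submitters' processing notes for those samples name TopHat2, HTSeq, Bowtie2 2.2.0, SAMtools 0.1.19 and MACS2 2.1.1 with builds mm9 and mm10, without saying which served the RNA. Every positive normalised value was a whole multiple of the value of 1 read in its library (100% of values, tolerance 0.001), which gave whole reads per gene and each library's depth. The depth behind the RPKM values is unknown, and their sums per library ran from 324114 to 344923. The male NAc table used here held 16239 genes and the table of the other libraries 32421, of which 27351 had a symbol, and the male VTA table held 37991, of which 181 without values were left out. Genes absent from the male NAc table used here, among them Ttr, Th and Ddx3x, were not analysed for that region. The 3 tables were normalised separately, and each test stayed within a table.

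Groups came from the titles and characteristics of the 163 RNA samples. Of 114 group-coded titles, 104 went with the characteristics in sex and adult condition. For 10 female NAc libraries, called misfiled here, the adult label repeats the sex, so the title was used. The 16 chromatin and input samples were not analysed here. Libraries are separate tissue samples, and no label ties libraries of different regions to 1 mouse. All 328 pairs of libraries of 1 group in the whole-read tables differed by more than sampling noise, with a lowest chi-square per gene of 2.80 (median 13.9, genes with at least 10 reads), so none was merged.

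Each region and sex was fitted with limma 3.58.1 (R 4.3.3, trend and robust) on log2(value + 1), with 1 coefficient per group, and 35 contrasts were tested with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The 14000 genes of highest mean were tested, or in male VTA the 14586 with a mean RPKM of at least 0.5. The contrasts, the filters, the rule for named genes, the first set of alternatives and 22 gene lists were chosen from the labels alone. The design allowed for raw counts, log values or normalised values. As the values were normalised, limma was used. Lists were tested with camera at a preset correlation of 0.01 (at least 3 measured members, adjusted over the lists of a contrast), with an estimated correlation, and with fry, which asks whether members move on balance 1 way and does not compare them with other genes. Adjusted p-values in the text come from limma and camera (limma) unless edgeR is named. Where fewer than 5 genes passed, the rule names the 3 higher and 3 lower genes of smallest p, plus members of a described list with their values and sex-linked and region marker genes as a check of the labels. Values of some single genes that the rule would name are not reported here.

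Alternatives fixed in advance were no filter, quantile normalisation, log2(RPKM + 0.1), the replicate number as a block, leaving out each library, leaving out the misfiled libraries, and the other list tests. Chosen after seeing the data were edgeR 4.0.16 on the recovered reads, 2 surrogate variables (sva 3.50.0), a minimum mean of 10 in male NAc, exact permutation of list values, and leaving out 14 doubted libraries. A library was doubted if Xist exceeded 200 normalised reads in a male, Ddx3y exceeded 50 or Xist lay under 0.5 of the region median in a female, or Ttr exceeded 10000; 100 splits were drawn at most where other splits of the samples were tested. Simulated values for the ELS contrast of the 7 region and sex sets were tested first. Of 100 genes changed by a log2 fold of 1 limma recovered 97 to 100, and 86 to 98 of 100 changed by 0.5. False calls were 6 to 12. The list shifted by 0.5 was called in all 7, and 1 list not shifted in male VTA. Other splits called up to 3819 genes, so these rates may not carry over.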

Results

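RNA was sequenced from adult C57BL/6 mouse brain to ask how early life stress (ELS), the disturbance of the nest during a set window of pup life, alters the adult response to a second stress. Adult males met chronic social defeat, repeated encounters with an aggressive male, and adult females met sub-threshold variable stress (STVS), a short series of changing stressors. The regions were the ventral tegmental area (VTA), where midbrain dopamine neurons lie, its target the nucleus accumbens (NAc), the prefrontal cortex (PFC) and, in males, the hippocampus (HIP). The 163 RNA libraries came from separate tissue samples taken 24 h after behavioural testing per the labels, and each male VTA or male NAc sample pooled punches of 3 mice. Male VTA held 4 standard controls, 4 ELS controls, 6 standard defeat and 6 ELS defeat libraries, and its labels do not give the ELS window. In male NAc, ELS on postnatal days 10 to 20 and ELS on days 2 to 12 were both used, with 4 standard controls, 6 standard defeat, 4 and 6 libraries of the later window and 4 and 5 of the earlier. Male PFC and male HIP held 6 libraries in each of 4 groups, and each female region held 6 standard controls, 5 standard STVS, 5 ELS controls and 6 ELS STVS libraries. Recovered reads per library ran from 13.6 to 23.9 M in male NAc, 27.9 to 36.0 M in male PFC and 22.4 to 42.7 M in male HIP. In females they ran from 19.2 to 41.2 M in VTA, 20.9 to 36.8 M in NAc and 22.4 to 34.4 M in PFC. The depth of the male VTA libraries is unknown.

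Sex-linked genes checked the labels. Ddx3y, a Y-linked helicase, lay between 1599 and 2317 normalised reads in every male NAc, PFC and HIP library, between 17.1 and 20.1 RPKM in male VTA, and at most at 145.0 in every female library. Xist, the RNA that coats the inactive X chromosome, was low in the female standard STVS library numbered 3 of each region, at 6152 normalised reads in VTA, 100.9 in NAc and 166.0 in PFC against region medians of 15463, 42172 and 28507. Male PFC standard defeat replicate 4 held 3853 normalised reads of the dopamine transporter Slc6a3, 2086 of the dopamine synthesis enzyme Th and 1284 of Xist. Female VTA standard control replicate 3 held 145.0 normalised reads of Ddx3y and the lowest Slc6a3 of its region, 7649. Ttr, the main transcript of the choroid plexus, lay between 28.2 and 250318 normalised reads in male HIP and reached 40770.3 in female NAc ELS STVS replicate 1. By fixed levels of Xist, Ddx3y and Ttr, 14 libraries were set apart as doubted, among them male PFC standard controls 1 and 4 (Xist up to 559.5) and 3 of 6 male HIP standard controls. The 23 of 35 comparisons that held one were also computed without them, chosen after seeing the data.

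**Figure D1:**
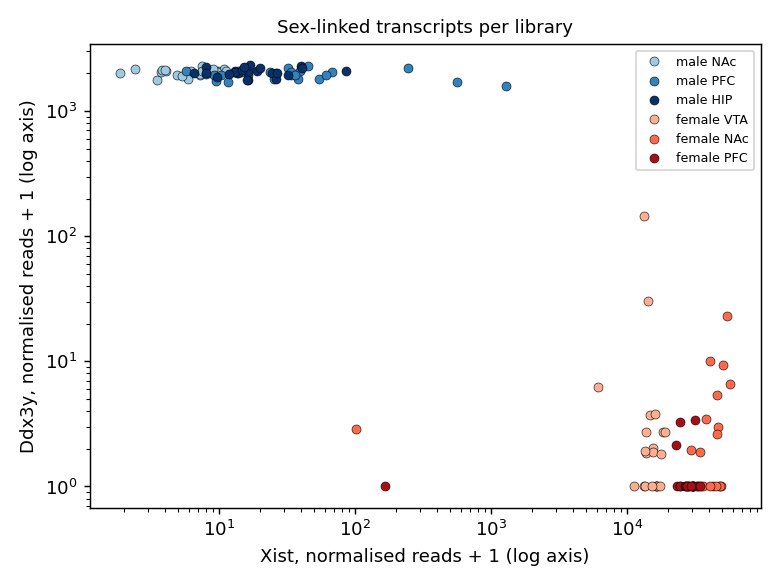
Xist (horizontal) against Ddx3y (vertical) in each library of male NAc, PFC and HIP and female VTA, NAc and PFC, in normalised reads + 1 on log axes. Male libraries hold 1599 reads of Ddx3y or more, and the female STVS libraries numbered 3 hold 100.9 of Xist in NAc and 166.0 in PFC.

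In all 35 comparisons limma called 0 genes at an adjusted p under 0.05, and edgeR called 0 in the 31 it was run on. Counts at an unadjusted p under 0.05, given with each below, ranged from 263 to 2011 where chance gives 700.0 (729 in male VTA). The differences that passed a test were those of gene lists fixed before the data were examined, tested with camera, which asks whether the members of a list rank higher or lower than the other genes. Of 739 list and comparison pairs camera called 157, with 61 of them kept whichever library was left out. With the correlation between members estimated from the residuals 1 pair was called, the blood list in male NAc after defeat, and by the directional test fry 3 were. Two-sided exact permutation of the mean list value gave an unadjusted p under 0.05 in 23 of 522 list and comparison pairs, no more than chance gives, and an adjusted p under 0.05 in 0. For each list the text gives the mean log2 fold change (log2FC) of its measured members, how many lay on that side of 0, how many libraries of the first group lay on that side of the mean of the second (not for interactions), and the adjusted p of camera with the preset and with the estimated correlation (the value marked estimated). After "ended" or "lost", a value in parentheses is the adjusted p of camera under that setting (sva stands for 2 surrogate variables) or without the library of that group and replicate number. After "stood apart" it is the gap to the next library over the group's range. A count of members past 0.05 when adjusted over the list alone (list-adjusted) is given where it was above 0, and over all genes it was 0 for every list. ELS, defeat or STVS, and both together are each set against the same standard controls of that region and sex, so these comparisons share chance.

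Defeat alone was compared with standard controls to find what adult stress did to males raised normally. In VTA, transcripts of red blood cells were more abundant after defeat: the blood list, haemoglobin chains and the haem synthesis enzyme Alas2, rose (log2FC 1.07, 5 of 5 members, 5 list-adjusted, 6 of 6 libraries, adjusted p = 2.56e-07, or 0.398 estimated). Hbb-b1 had a fold change of 2.28, from 30.6 ± 11.2 RPKM in controls (SD, n = 4) and 77.4 ± 45.1 in defeated males (SD, n = 6). The 4 haemoglobin genes are near-identical pairs that share reads, so the level of each is uncertain. Dopamine neuron transcripts rose as a group (log2FC 0.28, 16 of 18 members, 5 of 6 libraries, adjusted p = 2.38e-05, or 0.773 estimated). Members included Gch1 0.57 ± 0.26, Slc18a2 0.47 ± 0.28 and Ddc 0.47 ± 0.28 (log2 fold change ± SE) for the cofactor enzyme, the vesicular transporter and the decarboxylase, while the midbrain factor Lmx1a had -0.54 ± 0.25. The mitochondrial oxidative phosphorylation list rose (log2FC 0.08, 20 of 20 members, 4 of 6 libraries, adjusted p = 8.02e-06, or 0.773 estimated). Immediate early genes, which neurons switch on with activity, fell (log2FC -0.21, 15 of 16 members, 2 list-adjusted, 5 of 6 libraries, adjusted p = 0.00837, or 0.773 estimated). Of the members Fos -0.78 ± 0.20 and Egr1 -0.80 ± 0.23 fell list-adjusted. Of 14586 genes 0 passed with limma and 957 unadjusted. The immediate early call ended without standard defeat 2 (0.0565). Standard defeat replicate 6 stood apart as high in that list.

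In male NAc the blood list rose after defeat as well (log2FC 0.98, 5 of 5 members, 5 list-adjusted, 6 of 6 libraries, adjusted p = 1.29e-13, or 0.0247 estimated), and this was the call that held with an estimated correlation and with fry (adjusted p = 0.0170). Hbb-b1 rose list-adjusted, from 537 ± 79.0 normalised reads in controls (SD, n = 4) and 1136 ± 422 in defeated males (SD, n = 6), as did Alas2 (0.86 ± 0.26). Immediate early genes fell (log2FC -0.24, 12 of 14 members, 6 of 6 libraries, adjusted p = 0.000101, or 0.617 estimated), with Btg2 -0.36 ± 0.13 and Egr2 -0.71 ± 0.33. The myelin list was lower too (log2FC -0.10, 11 of 11 members, 4 of 6 libraries, adjusted p = 0.00229, or 0.819 estimated). The myelin call ended without standard control 3 (0.165) or 4 (0.133) or standard defeat 2 (0.0786) or 4 (0.180). Limma called 0 of 14000 genes, edgeR 0, and 474 unadjusted, Hbb-b1 and Hba-a2 being the named higher genes of smallest p. The immediate early call ended without standard control 3 (0.268).

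Defeat in male PFC went with lower immediate early genes, which fell as a list (log2FC -0.44, 20 of 20 members, 6 of 6 libraries, adjusted p = 2.29e-12, or 0.384 estimated). Values were Arc -1.21 ± 0.45, Nr4a1 -0.67 ± 0.24 and Dusp1 -0.68 ± 0.24, where Arc is a synaptic plasticity protein and Dusp1 a phosphatase that ends MAP kinase signals. The blood list rose (log2FC 1.13, 5 of 5 members, 6 of 6 libraries, adjusted p = 1.36e-05, or 0.384 estimated), where standard defeat replicate 2 stood apart as high (0.637). Dopamine neuron transcripts were called higher (log2FC 0.45, 9 of 10 members, 2 of 6 libraries, adjusted p = 0.0332, or 0.568 estimated), a call lost without the doubted libraries (0.185) and without standard control 1 (0.0522), 2 (0.0877) or 6 (0.113) or standard defeat 4 (0.149). Standard defeat replicate 4 stood apart as high in that list (0.799), and without it the list had the other sign. Oligodendrocyte precursor transcripts fell (log2FC -0.12, 9 of 10 members, 1 list-adjusted, 5 of 6 libraries, adjusted p = 0.00254, or 0.409 estimated). Of its members Gpr17 (-0.31 ± 0.08), a receptor of cells committed to become oligodendrocytes, fell list-adjusted. Heat shock transcripts fell (log2FC -0.10, 14 of 16 members, 5 of 6 libraries, adjusted p = 0.00248, or 0.409 estimated). Of 14000 genes 0 passed with limma or edgeR and 469 unadjusted, St6galnac3 (-0.43 ± 0.10) having the smallest. The heat shock call ended without the doubted libraries (0.250). The precursor call ended without standard control 5 (0.133). The striatal projection neuron list was lower as well (log2FC -0.31, 11 of 11 members, 6 of 6 libraries, adjusted p = 0.00178, or 0.409 estimated), and so was the myelin list (log2FC -0.17, 15 of 15 members, 3 of 6 libraries, adjusted p = 0.0464, or 0.700 estimated). Without the doubted libraries the striatal list had the other sign (adjusted p = 0.885). The myelin call ended with no filter (0.0673), with sva (0.477) and without standard control 3 (0.793) or 5 (0.765) or standard defeat 1 (0.439), 3 (0.109) or 6 (0.631). The striatal call ended without standard control replicate 4 as well (adjusted p = 0.233).

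In male HIP the blood list rose after defeat (log2FC 1.19, 5 of 5 members, 5 list-adjusted, 5 of 6 libraries, adjusted p = 3.42e-05, or 0.474 estimated). Oligodendrocyte precursor transcripts fell (log2FC -0.21, 9 of 10 members, 3 list-adjusted, 5 of 6 libraries, adjusted p = 0.00106, or 0.474 estimated), and the lineage factors Olig1 -0.30 ± 0.08 and Olig2 -0.42 ± 0.13 and C1ql1 (-0.39 ± 0.11) fell list-adjusted. Oxidative phosphorylation transcripts fell (log2FC -0.12, 17 of 20 members, 5 of 6 libraries, adjusted p = 8.9e-05, or 0.493 estimated). Interferon response genes rose (log2FC 0.34, 9 of 10 members, 5 of 6 libraries, adjusted p = 0.00181, or 0.493 estimated), with Ifit1 0.82 ± 0.34 and Oasl2 0.59 ± 0.23. Endothelial transcripts rose (log2FC 0.15, 9 of 12 members, 5 of 6 libraries, adjusted p = 0.0292, or 0.551 estimated), a call lost with sva (0.605), without the doubted libraries (0.145) and without standard control 1 (0.0502), 4 (0.0744) or 5 (0.0613) or standard defeat 3 (0.0886) or 5 (0.0820). Astrocyte transcripts rose (log2FC 0.13, 11 of 13 members, 5 of 6 libraries, adjusted p = 0.0141, or 0.501 estimated), a call lost with sva (0.539), without the doubted libraries (0.869) and without standard control 1 (0.0502). Synaptic receptor transcripts rose (log2FC 0.16, 15 of 20 members, 6 of 6 libraries, adjusted p = 0.0242, or 0.493 estimated), a call lost with sva (0.229), without the doubted libraries (0.720) and without standard control 1 (0.0684) or standard defeat 4 (0.0995). Glutamate neuron transcripts rose (log2FC 0.39, 11 of 14 members, 6 of 6 libraries, adjusted p = 0.0274, or 0.493 estimated), a call lost quantile-normalised (0.0743), with sva (0.518), without the doubted libraries (0.801) and without standard control 4 (0.0744) or standard defeat 1 (0.0858) or 4 (0.113). Its granule cell genes Prox1 and C1ql2 had 1.36 ± 0.63 and 1.58 ± 0.76. Choroid plexus transcripts fell (log2FC -3.64, 14 of 14 members, 6 of 6 libraries, adjusted p = 1.99e-06, or 0.493 estimated), and so did the myelin list (log2FC -0.56, 16 of 16 members, 6 of 6 libraries, adjusted p = 0.0002, or 0.501 estimated) and the heat shock list (log2FC -0.23, 16 of 16 members, 6 of 6 libraries, adjusted p = 0.000214, or 0.493 estimated). Standard defeat replicate 1 stood apart as low in the choroid plexus list. Ttr exceeded 10000 normalised reads in 3 of 6 standard controls and in 0 of 6 standard defeat libraries. Among 14000 genes tested, 0 passed with limma or edgeR, and 2011 unadjusted, with Trim8 (-0.29 ± 0.06) the smallest. Without the doubted libraries the choroid plexus, myelin and heat shock calls ended (adjusted p = 0.195, 0.317 and 0.317), and with sva these and the interferon call did (adjusted p = 0.518, 0.931, 0.518 and 0.119). The choroid plexus and astrocyte lists had the other sign under both settings.

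**Figure D2:**
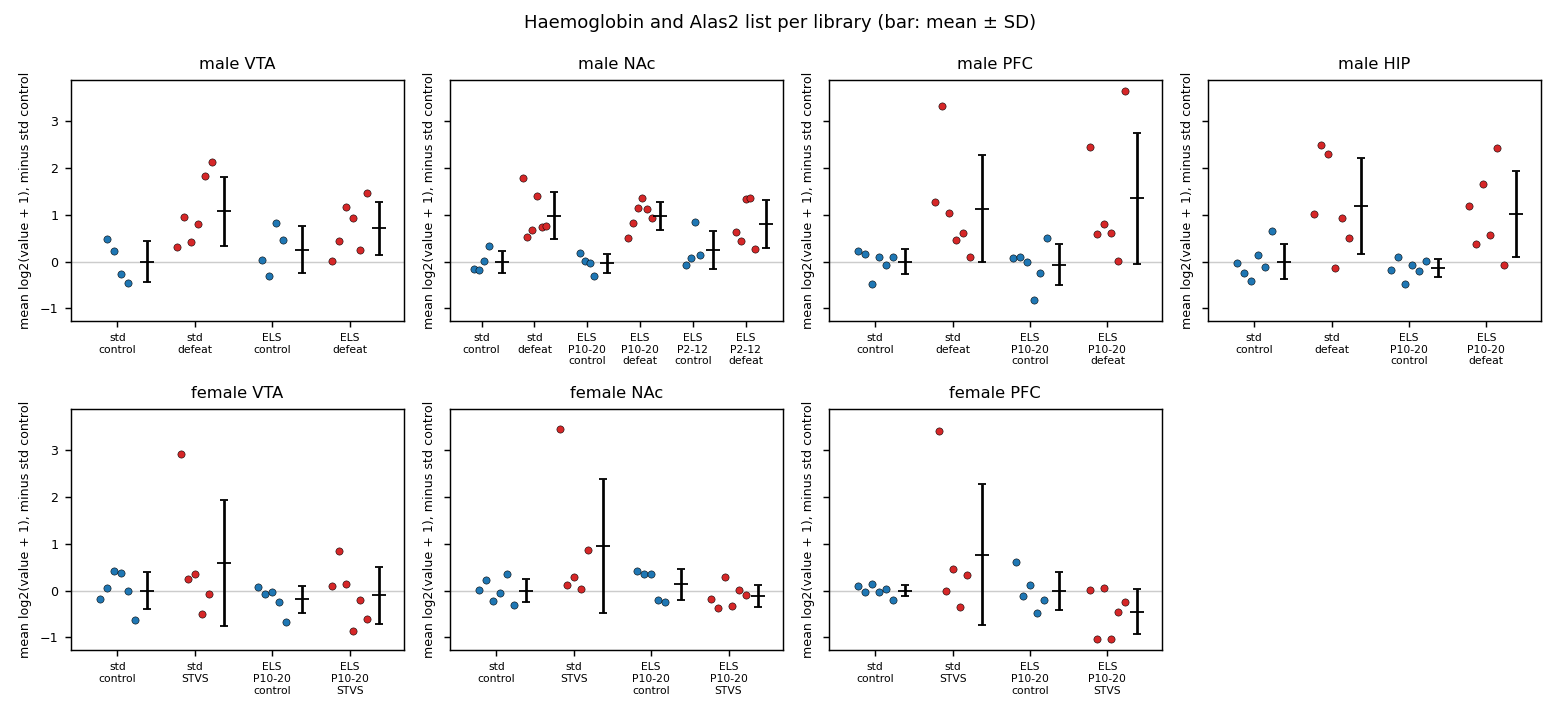
Mean log2 value of the blood list in each library (points) minus the mean of the standard controls of that region and sex, for 7 region and sex sets. Blue points are adult controls, red points are stressed mice, and bars show the group mean ± SD; after defeat the list was called higher in the 4 male regions, and with the estimated correlation in NAc alone (adjusted p = 0.0247, against 0.398 in VTA, 0.384 in PFC and 0.474 in HIP).

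ELS followed by no adult stress was compared with standard rearing to find what lasted into adulthood. In male VTA glucocorticoid-responsive genes, induced by the stress hormone corticosterone, fell (log2FC -0.15, 15 of 16 members, 1 list-adjusted, 4 of 4 libraries, adjusted p = 0.0176, or 0.982 estimated). Of its members Nfkbia (-0.33 ± 0.09), an inhibitor of NF-kappa-B, fell list-adjusted. The dopamine neuron list (log2FC 0.13, 16 of 18 members, 3 of 4 libraries, adjusted p = 0.0176, or 0.982 estimated) and the heat shock list (log2FC 0.03, 12 of 16 members, 1 of 4 libraries, adjusted p = 0.0353, or 0.982 estimated) were also called. ELS control replicate 3 stood apart as high in the heat shock list. At the gene level 0 of 14586 passed with limma, and 296 unadjusted. The glucocorticoid call ended without ELS control 1 (0.0775), 3 (0.419) or 4 (0.0741) or standard control 1 (0.280) or 2 (0.329). The dopamine neuron call ended with no filter (0.0687), quantile-normalised (0.246) and without ELS control 1 (0.902) or 4 (0.441) or standard control 3 (0.140) or 4 (0.450). The heat shock call ended with no filter (0.0961), quantile-normalised (0.246) and without ELS control 1 (0.0733), 3 (0.769) or 4 (0.0741) or standard control 1 (0.499) or 2 (0.287).

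In male NAc, ELS on days 10 to 20 moved 0 of the lists past camera's threshold, and 0 of 14000 genes passed with limma or edgeR while 948 passed an unadjusted p of 0.05. Mir199b (1.93 ± 0.40) and Zfp457 (-1.19 ± 0.25) had the smallest p on each side. With sva in the fit limma called 17 genes. After ELS on days 2 to 12 immediate early genes rose (log2FC 0.19, 12 of 14 members, 3 of 4 libraries, adjusted p = 0.00952, or 0.839 estimated), with Sik1 0.29 ± 0.10 and Btg2 0.21 ± 0.14. There 0 genes passed with limma or edgeR (484 unadjusted). That call ended without ELS P2-12 control 2 (0.417) or standard control 1 (0.585), the first of which stood apart as high in the heat shock list (0.918). Set directly against each other, the later window held lower endothelial transcripts than the earlier (log2FC -0.14, 9 of 9 members, 3 of 4 libraries, adjusted p = 0.00935, or 0.842 estimated), among them the receptor Flt1 (-0.21 ± 0.10) and the efflux pump Abcb1a (-0.15 ± 0.07). 0 genes differed between the windows with limma or edgeR (1070 unadjusted, with Skiv2l 0.26 ± 0.06 and Rpa1 -0.16 ± 0.04 the smallest on each side). Limma called 71 with sva and 70 without ELS P10-20 control replicate 3, and the endothelial call ended without ELS P2-12 control replicate 3 (adjusted p = 0.248).

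ELS in male PFC went with lower myelin and glucocorticoid-responsive transcripts. The mature oligodendrocyte and myelin list fell (log2FC -0.44, 15 of 15 members, 6 of 6 libraries, adjusted p = 2.07e-10, or 0.381 estimated). Members included Opalin -0.54 ± 0.26 and Mog -0.49 ± 0.29, genes of the myelin sheath. Glucocorticoid-responsive genes fell (log2FC -0.11, 14 of 17 members, 2 list-adjusted, 5 of 6 libraries, adjusted p = 1.7e-05, or 0.151 estimated). Of the members Sgk1 -0.21 ± 0.06 and Ddit4 -0.26 ± 0.07 fell list-adjusted. Striatal projection neuron transcripts fell (log2FC -0.39, 11 of 11 members, 6 of 6 libraries, adjusted p = 2e-06, or 0.381 estimated), with Gpr6 -1.06 ± 0.41 and Adora2a -0.86 ± 0.43. Gene by gene, 0 of 14000 passed with limma or edgeR and 311 unadjusted, Ppp1r10 (0.13 ± 0.03) and Sgk1 the smallest on each side. The striatal call ended without the doubted libraries (0.355).

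In male HIP after ELS alone choroid plexus transcripts fell (log2FC -2.70, 14 of 14 members, 5 of 6 libraries, adjusted p = 2.44e-06, or 0.794 estimated), and synaptic glutamate and GABA receptor transcripts rose (log2FC 0.15, 16 of 20 members, 6 of 6 libraries, adjusted p = 0.00334, or 0.450 estimated), with Grin1 0.15 ± 0.07 and Grm2 0.91 ± 0.66. Ttr exceeded 10000 normalised reads in 3 of 6 standard controls and 1 of 6 ELS controls, which are among the doubted libraries. Without the doubted libraries camera gave the choroid plexus list the other direction (adjusted p = 9.62e-05). As they were left out for high Ttr, a member of that list, this turn cannot be told from the effect of that choice. With sva the list was not called (adjusted p = 0.250). ELS control replicate 4 stood apart as high in that list. 0 of 14000 genes passed with limma or edgeR, and 904 unadjusted. The synaptic receptor call ended quantile-normalised (0.0740) and without the doubted libraries (0.621). Astrocyte transcripts rose (log2FC 0.10, 11 of 13 members, 5 of 6 libraries, adjusted p = 0.00823, or 0.794 estimated), a call lost quantile-normalised (0.264), with sva (0.362), without the doubted libraries (0.754) and without standard control 1 (0.0527). Microglia transcripts rose (log2FC 0.08, 13 of 14 members, 4 of 6 libraries, adjusted p = 0.00896, or 0.840 estimated), a call lost with sva (0.250), without the doubted libraries (0.256) and without ELS control 6 (0.400) or standard control 1 (0.281). Perineuronal net transcripts rose (log2FC 0.08, 8 of 12 members, 6 of 6 libraries, adjusted p = 0.0234, or 0.312 estimated), a call lost quantile-normalised (0.146) and without ELS control 3 (0.0540), 5 (0.0631) or 6 (0.0519) or standard control 1 (0.0527) or 5 (0.183). Oxidative phosphorylation transcripts fell (log2FC -0.07, 17 of 20 members, 5 of 6 libraries, adjusted p = 0.00896, or 0.858 estimated), a call lost with sva (0.205) and without ELS control 3 (0.339) or standard control 1 (0.0527) or 5 (0.189).

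Males with both ELS and defeat were compared with standard controls to find the joint effect. In VTA glucocorticoid-responsive genes fell (log2FC -0.20, 13 of 16 members, 3 list-adjusted, 6 of 6 libraries, adjusted p = 3.32e-07, or 0.382 estimated). Of the members Nfkbia -0.45 ± 0.08, Ddit4 -0.42 ± 0.08 and Sgk1 -0.87 ± 0.24 fell list-adjusted. Immediate early genes fell (log2FC -0.19, 13 of 16 members, 1 list-adjusted, 6 of 6 libraries, adjusted p = 1.88e-05, or 0.382 estimated), Fos (-0.74 ± 0.20) adjusted over the list alone. The blood list rose (log2FC 0.71, 5 of 5 members, 6 of 6 libraries, adjusted p = 1.61e-05, or 0.382 estimated). Endothelial transcripts fell (log2FC -0.09, 12 of 12 members, 5 of 6 libraries, adjusted p = 0.00101, or 0.604 estimated), a call lost without ELS defeat 1 (0.0679) or 5 (0.101) or standard control 1 (0.0766) or 2 (0.246). The myelin list fell (log2FC -0.09, 13 of 16 members, 3 of 6 libraries, adjusted p = 0.0128, or 0.663 estimated), a call lost without ELS defeat 1 (0.908), 5 (0.360) or 6 (0.0597) or standard control 2 (0.969). Without ELS defeat replicate 1 or standard control replicate 2 the myelin list had the other sign. Oligodendrocyte precursor transcripts fell (log2FC -0.06, 10 of 11 members, 6 of 6 libraries, adjusted p = 0.0309, or 0.465 estimated), a call lost without ELS defeat 1 (0.287), 2 (0.0688) or 5 (0.163) or standard control 1 (0.204) or 2 (0.235). Dopamine neuron transcripts rose (log2FC 0.12, 15 of 18 members, 4 of 6 libraries, adjusted p = 0.0309, or 0.663 estimated), a call lost with no filter (0.0736), quantile-normalised (0.102) and without ELS defeat 2 (0.157), 3 (0.396), 4 (0.254) or 6 (0.0938) or standard control 2 (0.0570), 3 (0.316) or 4 (0.538). Oxidative phosphorylation transcripts rose (log2FC 0.05, 20 of 20 members, 3 of 6 libraries, adjusted p = 0.000883, or 0.663 estimated), a call lost without ELS defeat 2 (0.712) or 3 (0.0514) or standard control 4 (0.0515). Of 14586 genes 0 passed with limma, and 368 unadjusted, Nfkbia having the smallest (adjusted p = 0.413).

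In NAc both ELS windows, each followed by defeat, went with more blood and fewer immediate early and myelin transcripts. After days 10 to 20 the blood list rose (log2FC 0.98, 5 of 5 members, 5 list-adjusted, 6 of 6 libraries, adjusted p = 3.33e-11, or 0.0582 estimated). Immediate early genes fell (log2FC -0.32, 13 of 14 members, 5 list-adjusted, 6 of 6 libraries, adjusted p = 1.2e-06, or 0.526 estimated), with Fos -0.91 ± 0.33 and Btg2 -0.43 ± 0.13. The myelin list fell (log2FC -0.16, 11 of 11 members, 5 of 6 libraries, adjusted p = 4.84e-06, or 0.526 estimated), with Mobp -0.27 ± 0.09 and Mal -0.19 ± 0.09. Choroid plexus transcripts rose (log2FC 1.01, 8 of 8 members, 4 of 6 libraries, adjusted p = 0.00730, or 0.526 estimated), a call lost without ELS P10-20 defeat 4 (0.550), which stood apart as high (0.845). Oligodendrocyte precursor transcripts fell (log2FC -0.09, 6 of 8 members, 5 of 6 libraries, adjusted p = 0.0404, or 0.526 estimated), a call lost without standard control 3 (0.284) or 4 (0.0585) or ELS P10-20 defeat 1 (0.189), 4 (0.130) or 6 (0.0797). After days 2 to 12 the blood list rose (log2FC 0.80, 5 of 5 members, 5 list-adjusted, 5 of 5 libraries, adjusted p = 2.25e-08, or 0.174 estimated). Immediate early genes fell (log2FC -0.31, 13 of 14 members, 4 of 5 libraries, adjusted p = 1.21e-06, or 0.476 estimated), with Junb -0.44 ± 0.16 and Egr2 -0.81 ± 0.34. The same held for the myelin list (log2FC -0.15, 11 of 11 members, 4 of 5 libraries, adjusted p = 3.44e-05, or 0.586 estimated). Endothelial transcripts fell (log2FC -0.12, 9 of 9 members, 4 of 5 libraries, adjusted p = 0.00362, or 0.586 estimated), a call lost without ELS P2-12 defeat 4 (0.141) or 5 (0.0581) or standard control 1 (0.0861) or 2 (0.106). Striatal projection neuron transcripts fell (log2FC -0.12, 8 of 8 members, 3 of 5 libraries, adjusted p = 0.0263, or 0.714 estimated), a call lost quantile-normalised (0.0501), with sva (0.634) and without ELS P2-12 defeat 1 (0.545) or 3 (0.150) or standard control 2 (0.348). Limma called 0 of 14000 genes in both, edgeR 0 in both, and 800 and 559 unadjusted, with Wnt3 (-0.57 ± 0.12) and Csrnp1 (-0.37 ± 0.10) the lower genes of smallest p.

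In male PFC after ELS and defeat camera called immediate early and myelin lists lower and microglia, endothelial and blood lists higher. Immediate early genes fell (log2FC -0.57, 18 of 20 members, 13 list-adjusted, 6 of 6 libraries, adjusted p = 1.64e-12, or 0.280 estimated), with Arc -1.43 ± 0.45 and Dusp1 -1.06 ± 0.24. ELS defeat replicate 5 stood apart as high in that list. The myelin list fell (log2FC -0.59, 15 of 15 members, 6 of 6 libraries, adjusted p = 6.52e-10, or 0.280 estimated), with Mobp -0.83 ± 0.36 and Mal -0.69 ± 0.28. Microglia transcripts rose (log2FC 0.15, 13 of 14 members, 4 list-adjusted, 4 of 6 libraries, adjusted p = 2.08e-07, or 0.280 estimated). Of the members Csf1r 0.18 ± 0.05, P2ry12 0.20 ± 0.06, Itgam 0.22 ± 0.07 and Cx3cr1 0.15 ± 0.06 did so list-adjusted. Endothelial transcripts rose (log2FC 0.16, 12 of 12 members, 4 of 6 libraries, adjusted p = 3.07e-06, or 0.280 estimated). Members included Kdr 0.27 ± 0.09 and Flt1 0.24 ± 0.09, receptors for vascular growth factor. The blood list rose (log2FC 1.35, 5 of 5 members, 5 list-adjusted, 6 of 6 libraries, adjusted p = 1.56e-05, or 0.280 estimated). Limma and edgeR called 0 of 14000 genes, and 1207 passed unadjusted. With sva limma called 4, and without standard control replicate 3 it called 1. The astrocyte list was higher as well (log2FC 0.11, 13 of 13 members, 4 of 6 libraries, adjusted p = 0.000793, or 0.407 estimated), and the glucocorticoid (log2FC -0.08, 11 of 17 members, 2 list-adjusted, 4 of 6 libraries, adjusted p = 0.00941, or 0.280 estimated) and heat shock lists were lower (log2FC -0.08, 15 of 16 members, 5 of 6 libraries, adjusted p = 0.0130, or 0.470 estimated). The astrocyte call ended without ELS defeat 6 (0.0552). The glucocorticoid call ended without the doubted libraries (0.0662) and without ELS defeat 3 (0.0680) or standard control 4 (0.0625). The heat shock call ended without the doubted libraries (0.416) and without standard control 1 (0.0615) or 4 (0.130).

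**Figure D3:**
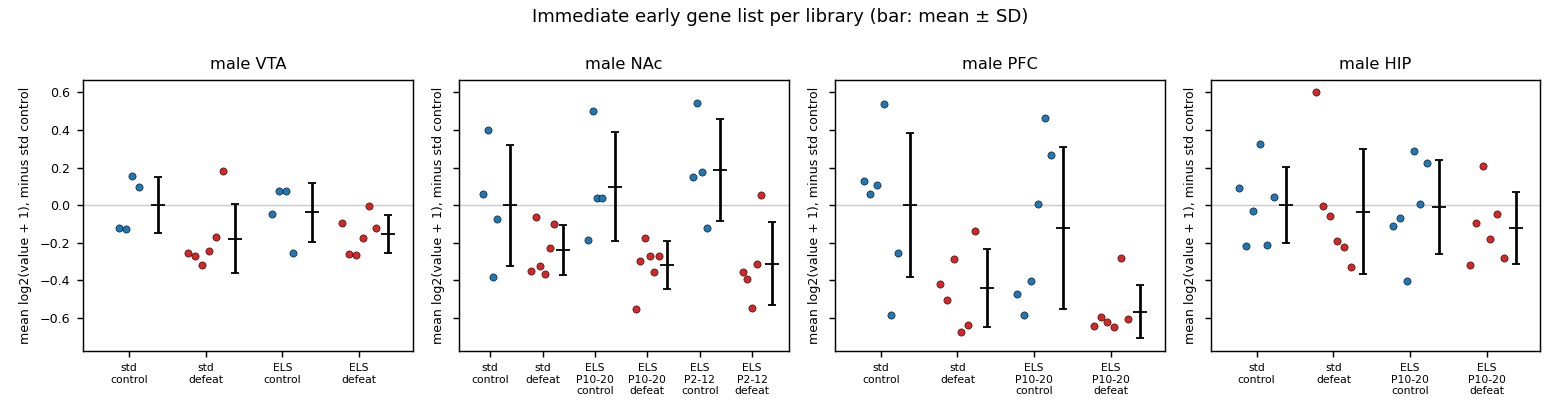
Mean log2 value of the immediate early list in each male library (points) minus the mean of the standard controls of its region, in the 4 male regions. Blue points are adult controls, red points are defeated males, bars show the group mean ± SD, and in PFC both defeated groups were called lower (adjusted p = 0.384 after defeat and 0.280 after ELS and defeat with the estimated correlation).

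In male HIP after ELS and defeat endothelial transcripts rose (log2FC 0.25, 12 of 12 members, 1 list-adjusted, 4 of 6 libraries, adjusted p = 1.48e-08, or 0.210 estimated). Of its members Slco1a4 (0.25 ± 0.07), a transporter of the blood-brain barrier, did so list-adjusted. Interferon response genes rose (log2FC 0.35, 9 of 10 members, 4 of 6 libraries, adjusted p = 9.83e-06, or 0.295 estimated), with Oasl2 0.54 ± 0.23 and Isg15 0.52 ± 0.24. The blood list rose (log2FC 1.02, 5 of 5 members, 5 list-adjusted, 5 of 6 libraries, adjusted p = 1.27e-07, or 0.210 estimated). Heat shock transcripts fell (log2FC -0.15, 15 of 16 members, 6 of 6 libraries, adjusted p = 0.000235, or 0.719 estimated), with Manf -0.30 ± 0.11 and Hspa5 -0.37 ± 0.20. The myelin list (log2FC -0.34, 16 of 16 members, 4 of 6 libraries, adjusted p = 0.00115, or 0.728 estimated) and the choroid plexus list (log2FC -1.15, 14 of 14 members, 4 of 6 libraries, adjusted p = 0.0397, or 0.728 estimated) were lower too. The myelin call ended with sva (0.477) and without ELS defeat 1 (0.188) or standard control 4 (0.157). The choroid plexus call ended with sva (0.0823) and without ELS defeat 1 (0.465), 3 (0.290), 4 (0.223) or 6 (0.229) or standard control 1 (0.579), 4 (0.717) or 6 (0.596). Without the doubted libraries the choroid plexus list was called in the other direction (adjusted p = 0.000766), and it had that sign with surrogate variables. At the gene level 0 of 14000 passed with limma or edgeR, and 477 unadjusted. The heat shock call ended without the doubted libraries (0.815). ELS defeat replicate 1 stood apart as low in that list.

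**Figure D4:**
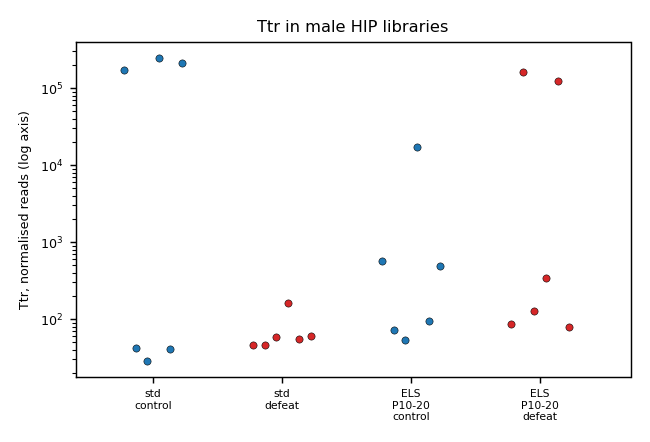
Ttr in normalised reads (log axis) in each male HIP library by group. The libraries range from 28.2 to 250318, and those above 10000 number 3 of 6 standard controls, 0 standard defeat, 1 ELS control and 2 ELS defeat.

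Whether ELS altered the response to defeat was tested as an interaction, the effect of defeat after ELS minus its effect after standard rearing. The closing section gives the adjusted p of every list called in one. In VTA the dopamine neuron list (log2FC -0.29, 16 of 18 members, adjusted p = 0.000501, or 0.869 estimated) and the myelin list (log2FC -0.17, 14 of 16 members, adjusted p = 0.000386, or 0.869 estimated) were lower in this difference, with Gch1 -0.61 ± 0.37, En2 -0.52 ± 0.33 and Mobp -0.28 ± 0.18. Gene by gene, 0 of 14586 passed with limma and 797 unadjusted, Gm15347 (0.67 ± 0.12) having the smallest. The dopamine neuron call ended quantile-normalised (0.0523) and without ELS control 1 (0.0901). The myelin call ended quantile-normalised (0.0523) and without ELS defeat 1 (0.0502).

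In NAc the interaction for ELS on days 10 to 20 moved 0 lists past camera's threshold and 0 genes past limma's or edgeR's (550 unadjusted). For days 2 to 12 striatal projection neuron transcripts were lower (log2FC -0.31, 8 of 8 members, adjusted p = 0.00105, or 0.924 estimated). Their values were Gpr6 -0.41 ± 0.15, Penk -0.29 ± 0.14 and Adora2a -0.35 ± 0.18, markers of the indirect pathway. 0 of 14000 genes passed with limma or edgeR (844 unadjusted), Mrps36-ps2 (2.55 ± 0.47, limma adjusted p = 0.0757) coming closest, and limma called 1 gene with no filter.

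In male PFC astrocyte transcripts (log2FC 0.20, 13 of 13 members, adjusted p = 2.63e-05, or 0.517 estimated) and endothelial transcripts (log2FC 0.20, 12 of 12 members, adjusted p = 7.88e-05, or 0.517 estimated) were higher in the interaction. Values were Aqp4 0.24 ± 0.11 and Slc1a2 0.19 ± 0.09 for the water channel and the glutamate transporter of astrocytes, and Cldn5 0.27 ± 0.14 for the tight junction protein of endothelium. The striatal list was higher as well (log2FC 0.50, 10 of 11 members, adjusted p = 0.00130, or 0.527 estimated). Of 14000 genes 0 passed with limma or edgeR, and 832 unadjusted, Slc7a7 (-0.71 ± 0.16) and Myd88 (0.39 ± 0.10) having the smallest on each side. The striatal call ended with sva (0.0537) and without the doubted libraries (0.286).

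In male HIP oxidative phosphorylation transcripts were higher in the interaction (log2FC 0.15, 20 of 20 members, adjusted p = 0.000296, or 0.689 estimated), with Atp5l 0.28 ± 0.10 and Uqcrb 0.20 ± 0.08. Choroid plexus transcripts were higher (log2FC 5.18, 14 of 14 members, 8 list-adjusted, adjusted p = 1.22e-07, or 0.649 estimated) and synaptic receptor transcripts lower (log2FC -0.29, 16 of 20 members, adjusted p = 0.00137, or 0.649 estimated), alongside the uneven Ttr levels given above for the 4 groups. Among 14000 genes tested, 0 passed with limma or edgeR, and 1649 unadjusted, among them Polr1d (0.33 ± 0.08) and Kcna2 (-0.55 ± 0.13). The choroid plexus call ended with sva (0.196) and without the doubted libraries (0.189), then with the other sign. The synaptic receptor call ended without the doubted libraries (0.161).

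Females, a separate cohort, were compared in the same way, with STVS as the adult stress. In female VTA after ELS alone heat shock transcripts rose (log2FC 0.08, 12 of 16 members, 3 list-adjusted, 4 of 5 libraries, adjusted p = 0.00246, or 0.773 estimated). Of the members Creld2 0.28 ± 0.08, Pdia4 0.16 ± 0.05 and Hspa5 0.14 ± 0.04, all 3 chaperones or folding factors of the endoplasmic reticulum, did so list-adjusted. At the gene level 0 of 14000 passed with limma or edgeR, and 591 unadjusted, the potassium channel Kcnj5 (0.52 ± 0.12) having the smallest. The heat shock call ended without ELS control 2 (0.0931). Astrocyte transcripts rose (log2FC 0.10, 10 of 13 members, 4 of 5 libraries, adjusted p = 0.0252, or 0.773 estimated), a call lost without ELS control 3 (0.159) or 4 (0.0954) or standard control 1 (0.0639), 2 (0.0710) or 6 (0.0593).

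STVS alone in female VTA went with more dopamine neuron transcripts (log2FC 0.39, 16 of 18 members, 4 of 5 libraries, adjusted p = 1.18e-05, or 0.749 estimated), with Pitx3 0.72 ± 0.34 and Slc6a3 0.70 ± 0.39. The standard control numbered 3 held the lowest Slc6a3 of the region. Gene by gene, 0 of 14000 passed with limma or edgeR (621 unadjusted, with Thumpd1 0.18 ± 0.04 and Atg2a -0.17 ± 0.04 the smallest on each side). The dopamine neuron call ended with sva (0.460) and without the doubted libraries (0.0606). Microglia transcripts rose (log2FC 0.05, 12 of 14 members, 3 of 5 libraries, adjusted p = 0.0415, or 0.749 estimated), a call lost with sva (0.0950), without the doubted libraries (0.0826) and without standard control 1 (0.0604), 3 (0.157) or 6 (0.476) or standard STVS 2 (0.0509) or 5 (0.411). The blood list rose (log2FC 0.59, 5 of 5 members, 3 of 5 libraries, adjusted p = 0.0415, or 0.749 estimated), a call lost without the doubted libraries (0.0606) and without standard control 1 (0.117), 2 (0.106), 5 (0.0731) or 6 (0.151) or standard STVS 1 (0.973) or 3 (0.102). Standard STVS replicate 1 stood apart as high in the blood list, and without it the list had the other sign.

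After ELS and STVS female VTA again held more dopamine neuron transcripts (log2FC 0.37, 16 of 18 members, 6 of 6 libraries, adjusted p = 0.000154, or 0.739 estimated), with Nr4a2 0.61 ± 0.28 and Pitx3 0.65 ± 0.33. Oxidative phosphorylation transcripts fell (log2FC -0.11, 20 of 20 members, 5 of 6 libraries, adjusted p = 2.55e-05, or 0.739 estimated), and so did the myelin list (log2FC -0.15, 16 of 16 members, 5 of 6 libraries, adjusted p = 0.000334, or 0.739 estimated). 0 of 14000 genes passed with limma or edgeR, and 1625 unadjusted, among them Nucb2 (0.27 ± 0.07) and Id2 (-0.21 ± 0.05). The oxidative phosphorylation call ended with sva (adjusted p = 0.961), and the dopamine neuron list then had the other sign (0.961). Striatal projection neuron transcripts rose (log2FC 0.21, 9 of 11 members, 6 of 6 libraries, adjusted p = 0.0362, or 0.739 estimated), a call lost with sva (0.102) and without ELS STVS 3 (0.0512) or standard control 5 (0.0738) or 6 (0.0636).

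In the female VTA interaction interferon response transcripts were higher (log2FC 0.16, 9 of 11 members, adjusted p = 0.00176, or 0.792 estimated), with Oasl2 0.45 ± 0.23 and Bst2 0.40 ± 0.17. Of 14000 genes 0 passed with limma or edgeR (332 unadjusted, with Ybx2 0.86 ± 0.23 and Magohb -0.48 ± 0.13 the smallest on each side). The interferon call ended without ELS STVS 4 (0.0954).

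Female NAc after ELS alone held more heat shock transcripts (log2FC 0.13, 15 of 16 members, 5 of 5 libraries, adjusted p = 0.00303, or 0.842 estimated), with Hspa5 0.26 ± 0.11 and Creld2 0.20 ± 0.07. Among 14000 genes tested, 0 passed with limma or edgeR, and 1569 unadjusted, the guidance receptor Epha3 (0.45 ± 0.11) having the smallest among those higher. The heat shock call ended with sva (0.0613), without the misfiled libraries (0.566) and without ELS control 2 (0.0780) or 4 (0.0573).

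After STVS alone female NAc held more oxidative phosphorylation transcripts (log2FC 0.18, 20 of 20 members, 5 of 5 libraries, adjusted p = 8.04e-10, or 0.544 estimated), with Ndufs6 0.22 ± 0.10 and Atp5l 0.21 ± 0.09. There were also more blood transcripts (log2FC 0.95, 5 of 5 members, 5 of 5 libraries, adjusted p = 0.000236, or 0.544 estimated). Synaptic receptor transcripts fell (log2FC -0.11, 18 of 20 members, 5 of 5 libraries, adjusted p = 0.00162, or 0.544 estimated), with Gabrb2 -0.37 ± 0.17 and Gria2 -0.19 ± 0.09. Standard STVS replicate 1 stood apart as high in the blood list (0.756). At the gene level 0 of 14000 passed with limma or edgeR, and 862 unadjusted, Fancb (-0.40 ± 0.09) having the smallest.

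After ELS and STVS female NAc held fewer striatal projection neuron transcripts (log2FC -0.16, 11 of 12 members, 4 of 6 libraries, adjusted p = 0.00294, or 0.622 estimated), with Rgs9 -0.30 ± 0.17 and Pde10a -0.36 ± 0.22. Heat shock transcripts rose (log2FC 0.09, 14 of 16 members, 5 of 6 libraries, adjusted p = 0.00106, or 0.459 estimated), and so did the choroid plexus list (log2FC 1.03, 6 of 6 members, 5 of 6 libraries, adjusted p = 0.000167, or 0.459 estimated), with Ttr at 40770.3 normalised reads in ELS STVS replicate 1. In the same comparison cortical glutamate neuron transcripts were lower (log2FC -0.88, 10 of 12 members, 5 of 6 libraries, adjusted p = 0.00892, or 0.459 estimated), with Slc17a7 at -2.37 ± 1.38, and subcortical neighbour transcripts higher (log2FC 0.30, 5 of 5 members, 4 of 6 libraries, adjusted p = 0.0428, or 0.459 estimated). The glutamate neuron call ended with sva (0.984, with the other sign), without the misfiled libraries (0.380) and without ELS STVS 6 (0.0596). The subcortical call ended with no filter (0.671), with sva (0.975), without the doubted libraries (0.0515) and without ELS STVS 1 (0.0503), 2 (0.331) or 5 (0.111) or standard control 1 (0.0534), 3 (0.0840) or 4 (0.128). Gene by gene, 0 of 14000 passed with limma or edgeR (454 unadjusted). The striatal call ended with sva (0.179). Endothelial transcripts fell (log2FC -0.08, 11 of 12 members, 5 of 6 libraries, adjusted p = 0.00684, or 0.459 estimated), a call lost without the misfiled libraries (0.568) and without ELS STVS 3 (0.369) or standard control 2 (0.0651). The myelin list fell (log2FC -0.09, 15 of 16 members, 3 of 6 libraries, adjusted p = 0.0352, or 0.896 estimated), a call lost with no filter (0.0703) and without ELS STVS 3 (0.692) or 6 (0.783) or standard control 2 (0.908). Standard control replicate 2 stood apart as high in the myelin list. Without the misfiled libraries the endothelial list had the other sign and the myelin list was called higher (adjusted p = 3.02e-08).

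The female NAc interaction held lower oxidative phosphorylation transcripts (log2FC -0.25, 20 of 20 members, adjusted p = 3.16e-08, or 0.771 estimated), with Uqcrb -0.26 ± 0.10 and Ndufa4 -0.27 ± 0.11. Blood transcripts were lower too (log2FC -1.19, 5 of 5 members, adjusted p = 0.00479, or 0.771 estimated). 0 of 14000 genes passed with limma or edgeR, and 1111 unadjusted, the RNA methyltransferase Nsun6 (0.41 ± 0.09) having the smallest.

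In female PFC after ELS alone heat shock transcripts rose (log2FC 0.10, 16 of 16 members, 4 of 5 libraries, adjusted p = 0.000111, or 0.877 estimated), with Manf 0.18 ± 0.07 and Sdf2l1 0.22 ± 0.11. Of 14000 genes 0 passed with limma or edgeR (460 unadjusted, with Otub2 0.19 ± 0.05 and Nfatc1 -0.35 ± 0.09 the smallest on each side). Microglia transcripts fell (log2FC -0.09, 13 of 14 members, 4 of 5 libraries, adjusted p = 0.00693, or 0.912 estimated), a call lost with no filter (0.0534), with sva (0.466) and without ELS control 2 (0.119) or 5 (0.102) or standard control 6 (0.542).

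STVS alone in female PFC went with more striatal projection neuron transcripts (log2FC 0.16, 7 of 10 members, 3 list-adjusted, 4 of 5 libraries, adjusted p = 0.0116, or 0.346 estimated). Of the members Pdyn 0.27 ± 0.08 and Pde10a 0.26 ± 0.08 rose list-adjusted. Oxidative phosphorylation transcripts rose (log2FC 0.08, 20 of 20 members, 4 of 5 libraries, adjusted p = 0.00290, or 0.663 estimated), with Cox5a 0.16 ± 0.06 and Uqcrb 0.13 ± 0.05. Among 14000 genes tested, 0 passed with limma or edgeR, and 706 unadjusted, the kinase Pim1 (0.49 ± 0.12) having the smallest among those higher. The striatal call ended without standard STVS 2 (0.256). The oxidative phosphorylation call ended with sva (0.289) and without standard STVS 5 (0.391). The blood list rose (log2FC 0.77, 5 of 5 members, 3 of 5 libraries, adjusted p = 0.0116, or 0.594 estimated), a call lost with sva (0.144) and without standard STVS 1 (0.670). Standard STVS replicate 1 stood apart as high in the blood list. GABA neuron transcripts rose (log2FC 0.11, 12 of 12 members, 4 of 5 libraries, adjusted p = 0.0149, or 0.594 estimated), a call lost with sva (0.289) and without standard control 2 (0.0724), 3 (0.0594) or 5 (0.0774) or standard STVS 2 (0.0513) or 5 (0.165).

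After ELS and STVS the myelin list rose in female PFC (log2FC 0.57, 16 of 16 members, 13 list-adjusted, 4 of 6 libraries, adjusted p = 1.31e-16, or 0.557 estimated). Examples were Mobp 0.80 ± 0.29 and Mbp 0.56 ± 0.21, both adjusted over the list alone, with Mobp at 5311 ± 717 normalised reads in controls (SD, n = 6) and 10412 ± 5701 in ELS STVS females (SD, n = 6). At the gene level 0 of 14000 passed with limma or edgeR (716 unadjusted, with Wipf3 0.21 ± 0.05 and Cyp26b1 -0.95 ± 0.24 the smallest on each side). The interaction in this region also had 0 genes past limma or edgeR (1108 unadjusted).

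**Figure D5:**
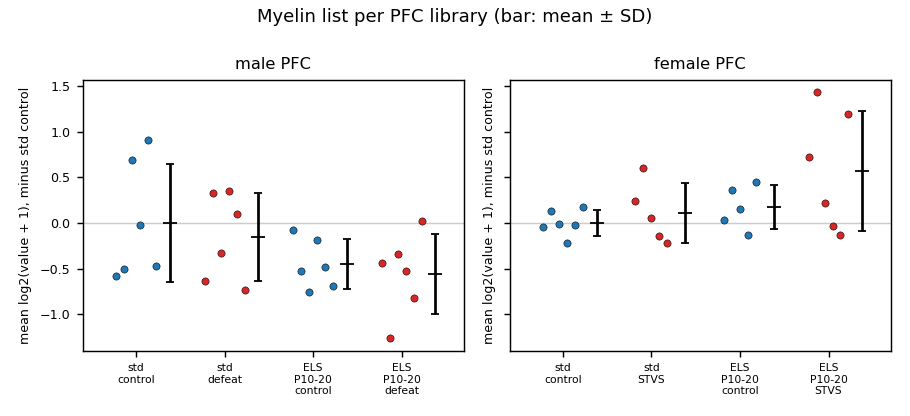
Mean log2 value of the mature oligodendrocyte and myelin list in each male and female PFC library (points) minus the mean of the standard controls of that sex. Blue points are adult controls, red points are stressed mice, and bars show the group mean ± SD; the means of both male ELS groups lie below the controls, and 4 of 6 female libraries with ELS and STVS lie above theirs.

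The effect of ELS alone in female PFC minus that in male PFC asked whether the sexes differed, with sex and cohort not separable. The myelin list was higher in females by this difference (log2FC 0.61, 15 of 15 members, adjusted p = 2.35e-10, or 0.538 estimated), with Mog 0.73 ± 0.40 and Gjb1 0.67 ± 0.41. Oxidative phosphorylation transcripts were higher (log2FC 0.13, 20 of 20 members, adjusted p = 2.23e-06, or 0.538 estimated) and microglia transcripts lower (log2FC -0.12, 14 of 14 members, adjusted p = 0.000159, or 0.538 estimated), with Itgam -0.28 ± 0.12 and Cx3cr1 -0.18 ± 0.11. Gene by gene, 0 of 14000 passed with limma or edgeR, and 263 unadjusted, Cnih4 (0.23 ± 0.06) having the smallest. The microglia call ended without female PFC standard control 6 (0.105). The oxidative phosphorylation call ended without male PFC ELS control 4 (0.121).

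The effect of ELS alone in male PFC minus that in male HIP was lower for the myelin list (log2FC -0.40, 16 of 16 members, adjusted p = 0.000868, or 0.707 estimated) and higher for the choroid plexus list (log2FC 2.28, 14 of 14 members, adjusted p = 1.8e-05, or 0.671 estimated). 0 of 14000 genes passed with limma or edgeR, and 525 unadjusted. The myelin call ended without male PFC standard control 5 (0.0782) or male HIP standard control 2 (0.0670). Without the doubted libraries the choroid plexus list was called in the other direction (adjusted p = 0.000517). Across VTA, NAc and PFC of females an F test found 0 genes whose ELS effect differed between regions (limma, edgeR 0, 683 unadjusted), and 1 without the misfiled NAc libraries.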

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

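The Y-linked test of low Xist, the VTA part of the single X test, the test of male VTA tissue and the test of choroid plexus by group were chosen only after the result was seen. Within groups of 4 to 6 libraries, a library was singled out when its gap to the nearest other exceeded Dixon's 95% limit as a share of the group's range. Of 236 group and measure sets 30 had such a library, where chance gives about 11.8.

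Low Xist set apart the female standard STVS library numbered 3 in VTA (0.737), NAc (0.915) and PFC (0.948). A male library under a female label is argued against, since the highest Y-linked gene in the 3 reached 0.371% of the male PFC median. A single X chromosome may account for PFC, where 4 of 4 genes escaping X inactivation, not looked at before, were lowest of 22 libraries. In NAc 2 of 4 were (6 of 8 in all). Utp14a there lay at 109% of the median of the others, so a single X stays open for NAc. A single X in every cell of the VTA library is argued against by Xist at 39.6% of the median of the other 21 libraries. Its Kdm6a, Eif2s3x, Ddx3x and Kdm5c were lowest too, at 77.5% to 88.5%. A mosaic loss and different mice behind 1 number stay open. Yet number 3, like number 1 for blood below, recurs in all 3 regions, so regions may share mice. Rearing and stress groups were not tested as a cause.

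In male PFC standard defeat replicate 4 the dopamine neuron list was high (0.799), with Slc6a3 at 3853 and Xist at 1284 normalised reads. RNA of a female VTA library in it may account for the levels. Xist stood at 8.12% of the female VTA level, and 14 dopamine genes not looked at before at a median of 10.8%. VTA tissue of the same male is argued against, as Xist would then lie near the other male PFC libraries (highest 559.5, this one 1284). Defeat as a cause was not tested, and the value rests on 1 of 6 libraries. Without this library the list's interaction call (0.0346, below) ended (0.93).

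Choroid plexus transcripts were high in 6 male HIP libraries, of which ELS control replicate 4 stood apart (0.730), while standard defeat replicate 1 stood apart as low (0.648). Choroid plexus tissue in the punch may account for this, since 1 tissue keeps its transcripts in 1 ratio and the median SD of the log2 ratio to Ttr over the 6 libraries was 0.217. The rearing and stress groups stay open: 3 of 6 standard controls, 0 of 6 standard defeat, 1 of 6 ELS control and 2 of 6 ELS defeat libraries were high (two-sided Fisher's exact p = 0.410), which at these numbers cannot be told apart from an even spread.

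Blood transcripts were high in female standard STVS replicate 1 of VTA (0.745), NAc (0.756) and PFC (0.783), and in male PFC standard defeat replicate 2 (0.637). Choroid plexus transcripts were high in male VTA ELS defeat replicate 1 (0.667), male NAc ELS P10-20 defeat replicate 4 (0.845), female VTA ELS STVS replicate 2 (0.634), female VTA standard control replicate 3 (0.816) and female NAc ELS STVS replicate 1 (0.871). Dopamine neuron transcripts were high in male NAc standard defeat replicate 5 (0.707), male PFC standard control replicate 5 (0.770), male HIP standard defeat replicate 5 (0.758) and female NAc standard control replicate 5 (0.768). Immediate early genes were high in male VTA standard defeat replicate 6 (0.700), male PFC ELS defeat replicate 5 (0.862) and male HIP standard defeat replicate 1 (0.650), and low in female PFC ELS control replicate 5 (0.770). Heat shock transcripts were high in male VTA ELS control replicate 3 (0.904), male NAc ELS P2-12 control replicate 2 (0.918) and female NAc standard STVS replicate 4 (0.744), and low in male HIP ELS defeat replicate 1 (0.646). The myelin list was high in female NAc standard control replicate 2 (0.699), Xist was low in female PFC ELS STVS replicate 2 (0.698), and male NAc standard defeat replicate 3 had few reads (0.695).

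Camera called a gene list in 46 direct tests of a difference between effects (adjusted p at the preset correlation in parentheses). Of these calls 12 were kept whichever library was left out. None was called with an estimated correlation, where adjusted p ran from 0.517 to 0.924, or by fry. In the male VTA interaction the lower lists were dopamine neuron (0.000501), myelin (0.000386), endothelial (0.0238) and blood (0.0196). In male NAc, for ELS on days 2 to 12, they were immediate early (0.0120), endothelial (0.0143) and striatal (0.00105), and between windows endothelial (0.00935). In male PFC dopamine neuron (0.0346) was lower, and oligodendrocyte precursor (0.0299), astrocyte (2.63e-05), microglia (0.00355), endothelial (7.88e-05), striatal (0.00130), oxidative phosphorylation (0.0212), perineuronal net (0.0201) and interferon (0.0195) were higher. In male HIP astrocyte (0.0182) and synaptic receptor (0.00137) were lower and choroid plexus (1.22e-07) and oxidative phosphorylation (0.000296) higher. In female VTA endothelial (0.0470) and oxidative phosphorylation (0.0470) were lower and interferon (0.00176) higher. In female NAc blood (0.00479) and oxidative phosphorylation (3.16e-08) were lower and synaptic receptor (0.0291) and H3K4 enzymes (0.0291) higher. In female PFC blood (0.0152), heat shock (0.0275) and oxidative phosphorylation (0.0206) were lower and myelin (0.0152) higher. The ELS effect in PFC was higher in females for glucocorticoid (0.0195), myelin (2.35e-10), striatal (0.000159) and oxidative phosphorylation (2.23e-06) and lower for microglia (0.000159) and H3K4 enzymes (0.0435). In males it was lower in PFC than in HIP for myelin (0.000868), astrocyte (0.00206), striatal (0.000868), GABA neuron (0.0400), synaptic receptor (0.0400) and perineuronal net (0.0400), and higher for choroid plexus (1.8e-05) and heat shock (0.0400).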

How the results depend on the processing

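EdgeR, the surrogate variables, the minimum mean of 10, the fits without doubted libraries and the permutation of list values were chosen only after the result was seen, and the other alternatives before. The count of genes past the threshold stayed at 0 in 35 contrasts under quantile normalisation, in 4 with log2(RPKM + 0.1), in 31 with edgeR, in 8 with a minimum mean of 10 and in 23 without doubted libraries. It became 1 with no filter for the male NAc interaction of the earlier window, and 1 without the misfiled libraries for the female region test. With 2 surrogate variables it became 17 for male NAc ELS alone, 71 for the later against the earlier window and 4 for male PFC ELS with defeat. Leaving out each library (508 fits) gave 0 to 70 genes between the NAc windows, the 70 without ELS P10-20 control replicate 3, and 0 to 1 in male PFC after ELS and defeat, the 1 without standard control replicate 3, and 0 elsewhere. Of the 157 list calls 1 held with an estimated correlation and 3 with fry. Of 112 that compare a pair of groups 0 held with an adjusted exact permutation p, which a single male VTA or NAc list could not. No filter kept 140 of 157 list calls, quantile normalisation 137 of 157, log2(RPKM + 0.1) 19 of 19, a minimum mean of 10 also 19 of 19, 2 surrogate variables 86 of 138, the fits without doubted libraries 68 of 119 and those without misfiled libraries 11 of 18, while 61 of 157 were kept whichever library was left out.

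Whether same-numbered libraries of the groups compared deviate together stayed open: in 0 of 18 contrasts was every correlation of same-numbered deviations over 0.1, though single correlations reached 0.604 and up to 4 of 6 exceeded 0.1, so the numbers were not taken to pair the samples. With the replicate number as a block 0 genes passed in the 25 contrasts that allowed it and 116 of 130 list calls were kept, none turning in direction, and as a random block over regions 0 genes passed in 2.

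List calls that turned in direction are given with their adjusted p under that setting, and the cause was not tested. Leaving out 1 library turned the male VTA myelin call after ELS and defeat (range 7.16e-06 to 0.969, turned without ELS defeat replicate 1 at 0.908 and without standard control replicate 2 at 0.969). After defeat in male PFC it turned the dopamine neuron call (range 0.00107 to 0.149, without standard defeat replicate 4 0.149) and the myelin call (range 0.000384 to 0.793, without standard control replicate 5 0.765). In female VTA after STVS it turned the blood call (range 0.000147 to 0.973, without standard STVS replicate 1 0.973). Without doubted libraries the calls that turned were dopamine neuron 0.185 and striatal 0.885 in male PFC after defeat, and in male HIP choroid plexus after ELS 9.62e-05, after defeat 0.195, after both 0.000766 and in the interaction 0.189. Also turned were the HIP astrocyte calls after defeat 0.869 and in the interaction 0.797, and between PFC and HIP astrocyte 0.901, choroid plexus 0.000517 and synaptic receptor 0.872. With 2 surrogate variables, in male HIP astrocyte 0.539 and choroid plexus 0.518 turned after defeat, choroid plexus 0.0823 after both and astrocyte 0.956 in the interaction. In females that setting turned oxidative phosphorylation in VTA after ELS 0.860 and in the PFC interaction 0.926, dopamine neuron in VTA after both 0.961, and glutamate neuron 0.984 and immediate early 0.984 in NAc after both. Without the misfiled libraries, in female NAc immediate early turned after STVS 0.850, and endothelial 0.568 and myelin 3.02e-08 after both.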

Other observations

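The split tests of the list counts and of the counts without surrogate variables were chosen only after the result was seen. The list of H3K4 monomethylation enzymes, which also holds other members of their complexes, was called in 5 of 34 contrasts, 3 higher and 2 lower. In female NAc after STVS the list fell (log2FC -0.09, 9 of 11 members, 4 of 5 libraries, adjusted p = 0.0182, or 0.696 estimated), with Kdm6a -0.22 ± 0.07, Mll3 -0.14 ± 0.08 and Setd7 -0.20 ± 0.17, and in male PFC after ELS it rose (log2FC 0.04, 10 of 11 members, 4 of 6 libraries, adjusted p = 0.0106, or 0.381 estimated), with Kdm2b 0.14 ± 0.05. Kdm6a, a complex member that acts on H3K27, is X-linked and escapes X inactivation, and it was lowest of 22 libraries in standard STVS replicate 3 (1331 normalised reads, 75.7% of the median of the others), where Xist was nearly absent. The first call ended with sva (0.263), without the doubted libraries (0.0609) and without standard control 3 (0.0607) or standard STVS 3 (0.0574) or 5 (0.0833). The second call ended quantile-normalised (0.0920), without the doubted libraries (0.196) and without ELS control 4 (0.195) or standard control 1 (0.0985) or 2 (0.0658).

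The CRF, vasopressin and oxytocin list and the sex hormone receptor list were called in 0 of 34 contrasts by camera, with smallest adjusted p of 0.0803 and 0.198. Other lists called between 2 groups, each lost without at least 1 library, were lower in male PFC after defeat glucocorticoid (0.0384, or 0.409 estimated), synaptic receptor (0.0139, or 0.493 estimated) and perineuronal net (0.0464, or 0.409 estimated), lower there after ELS oxidative phosphorylation (2e-06, or 0.564 estimated) and interferon (0.00263, or 0.381 estimated), higher in male NAc after later ELS and defeat oxidative phosphorylation (0.0410, or 0.526 estimated), lower in female VTA after ELS oxidative phosphorylation (0.0252, or 0.910 estimated) and after STVS interferon (0.00909, or 0.749 estimated), higher there after both H3K4 enzymes (0.0349, or 0.739 estimated), higher in female NAc after STVS immediate early (0.0182, or 0.948 estimated) and lower after both immediate early (0.0428, or 0.896 estimated), and higher in female PFC after STVS glucocorticoid (0.0123, or 0.594 estimated).

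Other splits of the same samples into groups of the same sizes were used to ask whether chance can be excluded for the number of lists called. Under 0.05 of the splits called as many lists in 2 of the 32 contrasts that called a list, defeat alone in male PFC (10 lists, 2 of 100 splits with as many, highest other 11) and in male HIP (11 lists, 3 of 100, highest other 11). About as many contrasts fall under that limit by chance when 32 are tested, and another split reached 11 lists in each, so chance cannot be excluded for these counts. Nor can it be for the others. Their number of splits with as many lists, the real one included, follows (lists called and highest other split in parentheses). In male VTA it was 27 of 35 for ELS (3, 10), 78 of 100 for defeat (4, 9), 19 of 100 for both (8, 11) and 61 of 100 for their interaction (4, 13). In male NAc it was 51 of 100 for defeat (3, 8) and 19 of 100 for both (6, 10), and with the earlier window 25 of 35 for ELS (1, 9), 24 of 100 for both (5, 6), 57 of 100 for the interaction (3, 8) and 33 of 35 for the windows (1, 7). In male PFC it was 44 of 100 for ELS (6, 12), 38 of 100 for both (8, 12) and 21 of 100 for the interaction (9, 11). In male HIP it was 27 of 100 for ELS (6, 10), 55 of 100 for both (6, 11) and 80 of 100 for the interaction (4, 11). In female VTA it was 90 of 100 for ELS (3, 12), 82 of 100 for STVS (4, 11), 60 of 100 for both (5, 10) and 76 of 100 for their interaction (3, 10). In female NAc it was 98 of 100 for ELS (1, 9), 72 of 100 for STVS (5, 11), 24 of 100 for both (8, 12) and 68 of 100 for their interaction (4, 11). In female PFC it was 86 of 100 for ELS (2, 12), 61 of 100 for STVS (5, 12), 98 of 100 for both (1, 10) and 64 of 100 for their interaction (4, 12). For the differences of ELS effects it was 39 of 100 for the sexes (6, 10) and 6 of 100 for PFC against HIP (8, 10).

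Where the real count is 0 every split gives as many, so the test decides nothing for male NAc ELS on days 10 to 20 (0 lists, 35 of 35 splits, highest other 5), for its interaction (0 lists, 100 of 100, highest other 8) or for the number of genes, 0 in each contrast. Some other splits called far more, up to 3819 genes for male VTA ELS and defeat, 2108 for female VTA STVS, 1468 for male HIP ELS and defeat and 1339 for female VTA ELS and STVS. What set these splits apart was not tested. With 2 surrogate variables, 71 genes were called between the NAc windows (1 of 35 splits with as many, highest other 32), 4 in male PFC after ELS and defeat (3 of 100, highest other 9) and 17 in male NAc after ELS (2 of 35, highest other 24). Only these 3 of the 31 contrasts fitted that way were split, because they had called genes, so chance cannot be excluded for them.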
